A study of Mus musculus with 39 samples.

How the data were processed

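Liver chromatin of male CD-1 mice aged 7 weeks was examined by ChIP-seq (chromatin immunoprecipitation followed by sequencing) for 3 histone marks. H3K27ac is found at active enhancers and promoters, H3K4me1 at enhancers in active or poised states, and H3K4me3 at promoters. Mice had received TCPOBOP at 3 mg/kg or the vehicle, 1% DMSO in corn oil. TCPOBOP is an agonist of the constitutive androstane receptor (CAR), a nuclear receptor of hepatocytes that controls drug-metabolising genes. Livers were collected 3 h after dosing from 3 TCPOBOP and 3 vehicle mice, and 27 h after dosing from 4 TCPOBOP and 3 vehicle mice. Within a time the same mice supplied all 3 marks, and different mice were used at the 2 times, which gave 39 libraries from 13 mice in 12 groups. At 3 h, isolated nuclei were crosslinked in 0.8% formaldehyde at 30 °C for 9 min 30 s, per the labels. At 27 h, frozen whole tissue was crosslinked in 1% formaldehyde at 22 °C for 10 min, per the labels. Time and chromatin preparation therefore changed together, and levels were not tested between times.

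The deposited files were lists of peaks called in each library separately, 39 lists in 12 files. Peaks were called with MACS 2.1.0.20150731 on paired-end fragments without a control library, at a q-value limit of 0.05, with an effective genome size of 1.87e+09 and a local background of 10000 bp, per the file headers. Alignment with Bowtie and the mouse build mm9 were named in the submitters' processing notes, and positions are given in mm9 as the files gave them. For each peak the authors deposited a pileup at the summit, which is a fragment coverage signal. They also deposited a fold enrichment over the local background, a ratio, and −log10 p and −log10 q values. These scores were the authors' own and served only to rank or filter peaks within their own list; the pileup was not used. The numbering of peaks in each list skipped 235 to 704 numbers (0.445% to 3.49%), for a reason not given in the sources used here. Libraries held 11288007 to 22192647 fragments, per the file headers. The lists give no count per region, so a missing peak meant that no peak passed the threshold at that depth, not that the mark was absent.

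Overlapping peaks (at least 1 bp) of all libraries of a mark and time were merged into regions. A region was termed TCPOBOP-only when every TCPOBOP library and no vehicle library had a peak in it, and vehicle-only in the reverse case. The number of such condition-only regions was set beside every other split of the same mice into groups of those sizes, 10 splits at 3 h and 35 at 27 h. A region was termed strong when at least 1 library ranked a peak in it in its top N by fold enrichment, N being the length of the shortest list divided by 4. Peak number, covered length and the share of peaks found in libraries of the other condition were compared by exact two-sided permutation tests, 18 tests with Benjamini-Hochberg adjustment. Such a test cannot fall below p = 0.1 with 3 against 3 libraries, or below p = 0.0571 with 4 against 3, both exact. Shares of regions carry exact Clopper-Pearson 95% intervals, which cover counting error only. To follow regions into other libraries, the percentage of vehicle-only regions with a peak was subtracted from that of TCPOBOP-only regions in each library, and these values were compared by the exact test in 30 combinations of region set and libraries.

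Called length in 10 kb windows was tested with limma 3.58.1 (R 4.3.3) on log2(called bp + 200), over windows with a mean of at least 500 bp, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes of windows are on this scale, which understates changes of windows with little called length. Separate fits for each mark and time were run first, then fits of both times with time as a term, each with and without subtracting library means. On simulated windows with 200 planted changes of 2 log2 units, the fit over both times recovered 98.0% for H3K27ac over 16708 windows with 16 false calls, 91.5% for H3K4me1 over 29318 windows with 11, and 99.5% for H3K4me3 over 9673 windows with 8. The separate fits recovered 78.0% to 99.0% of such changes. Noise in the simulated windows was normal and independent on the log2 scale, with no floor at 0 bp, unlike the real windows. Of changes of 1 log2 unit, the fits over both times recovered 77.0%, 44.5% and 84.0% for the marks in that order, and the separate fits at 3 h and 27 h 30.0% and 56.0% for H3K27ac, 0% and 0% for H3K4me1, and 37.5% and 79.5% for H3K4me3. On simulated peak lists of the real lengths, all 120 planted TCPOBOP-only and all 80 planted vehicle-only regions were recovered in each of the 6 comparisons. Each was planted in every library of its condition and in none of the other, so recovery was certain and checks the counting only. Unplanted regions also arose there by chance at the real list lengths: 0 TCPOBOP-only in all 6, and vehicle-only 23 and 20 for H3K27ac at 3 h and 27 h, 85 and 8 for H3K4me1, and 275 and 1 for H3K4me3. The 0 was fixed by construction, since the longest list, a vehicle list in all 6, held every unplanted region. Other splits of the real mice gave a median of 156 to 1012 at 3 h and 45 to 525 at 27 h, so the simulation sets no bound on the real lists. Other counts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

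The grouping, the overlap, condition-only, mark and between-time comparisons, the rule for named regions and the alternatives of overlap, strength, list length and replicate block were fixed before the data were examined. The regions taken by that rule were the 10 strong regions per direction ranked highest by mean fold percentile within their own lists (fewer where fewer were strong), and the 5 per direction called condition-only for the most marks and times. All of the strong ones enter the counts over named regions, while their positions are printed mainly for those ranked first, and the pair on chromosome 2 was chosen after its values were seen. That written rule asked for strong regions without saying in how many libraries, and asked for the highest fold enrichment without saying how lists combine. Both readings were chosen after the data were examined, because almost no region was strong in every library. The written design also allowed a count with or without the strength limit, so both are printed. The windows, the 30 combinations, the requirement of 2 libraries of a condition to call another mark, the tallies of regions shared between marks, the tallies of named regions in other libraries, every alternative for regions followed into the libraries of the other time, the −log10 q limit for peak number and the leave-one-out fits of overlap and windows were added after the data were examined. The mapped region was picked because its marks differ in opposite directions. Of the 2 scalings of windows, the fit without subtraction is the reported one, chosen with both counts known. Gene names were not attached to regions, because the gene table used here belongs to another build, so the 17 gene and cell-type lists fixed in advance were not used here.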

Results

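The libraries profiled H3K27ac, H3K4me1 and H3K4me3 in livers of mice given TCPOBOP, the CAR agonist, or vehicle, and addressed which regions gained or lost these marks 3 h and 27 h after dosing. Each mark was profiled in 3 TCPOBOP and 3 vehicle livers at 3 h, and in 4 and 3 livers at 27 h. H3K27ac libraries held 18368824 to 20935460 fragments at 3 h and 13125123 to 17178656 at 27 h. H3K4me1 libraries held 18897290 to 22192647 and 15893489 to 18159064, and H3K4me3 libraries 13442078 to 21158744 and 11288007 to 14083590. The number of peaks per library ran from 40606 to 50028 for H3K27ac at 3 h and from 29171 to 40421 at 27 h. H3K4me1 gave 75478 to 94114 peaks at 3 h and 47228 to 59606 at 27 h. H3K4me3 gave 15001 to 28264 and 15500 to 18243.

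At the authors' threshold, most peaks of a library were shared with libraries of the other condition. For H3K27ac, 77.1% of the peaks of a library were found in a library of the other condition at 3 h and 76.0% at 27 h. These shares were 77.4% and 63.0% for H3K4me1, and 73.9% and 85.7% for H3K4me3. When both lists were limited to peaks with −log10 q of at least 10, the H3K4me1 share at 27 h was 30.2%. Libraries of the same condition shared no more at that limit (within minus between conditions -0.621 points). TCPOBOP lists were shorter on average in all 6 comparisons. The exact test cannot decide on these differences, since its lowest possible p was 0.1 at 3 h and 0.0571 at 27 h. Leaving out a library turned the sign for H3K27ac at 3 h (1100 more peaks after TCPOBOP without vehicle replicate 3) and for H3K4me3 at 27 h (75 more without vehicle replicate 2). At 27 h, H3K27ac lists held 34162 ± 3702 peaks (SD, n = 4) after TCPOBOP and 37991 ± 2153 (SD, n = 3) after vehicle (exact two-sided p = 0.171). At 3 h, H3K4me3 lists held 20697 ± 4952 and 25773 ± 4080 peaks (SD, n = 3 each, exact two-sided p = 0.3). Depth there was 14394369, 13789895 and 17339569 fragments after TCPOBOP and 21158744, 20664178 and 13442078 after vehicle. For H3K27ac at 27 h it was 13125123 to 15257604 and 13754239 to 17178656. For H3K4me3 at 27 h it was 11288007 to 14083590 and 12427486 to 12988078. Peak numbers were not corrected for depth, and depth was not tested as a cause of the shorter TCPOBOP lists. Among the 18 tests of peak number, covered length and share in the other condition, the lowest exact p was 0.0571 (adjusted p = 0.343), the lowest possible at 27 h. The shares of H3K27ac and H3K4me1 at 27 h reached it, and those of H3K4me1 and H3K4me3 at 3 h reached their limit of 0.1. The shares of H3K27ac at 3 h and H3K4me3 at 27 h did not reach theirs, nor did any peak number or covered length. Libraries of H3K27ac at 27 h shared more peaks within a condition than between conditions, by 1.17 percentage points (exact one-sided p = 0.0286). The highest value of the other 34 splits was 0.975, and the share was not adjusted for the 6 comparisons. With lists of equal length the difference was 1.02 points (exact one-sided p = 0.0571). The other 5 comparisons gave differences of -0.269 to 0.547 points, with exact one-sided p values of 0.1 to 0.657. The 10 splits at 3 h allow no such p under 0.1. H3K4me1 at 3 h was at that limit, with 0.158 points in the real split and 0.145 at most in the others. With lists of equal length H3K27ac at 3 h was at it, while H3K4me1 and H3K4me3 were not (exact one-sided p = 0.1, 0.3 and 0.2).

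H3K27ac at 27 h stood apart from other splits of the same mice. In total 196 regions carried the mark in all 4 TCPOBOP livers and in no vehicle liver, and 345 regions carried it in all 3 vehicle livers and in no TCPOBOP liver. These 541 regions were 0.910% of 59439. Only the real split reached that number, 1 of 35 splits, and the other splits gave 404 at most, with a median of 212. The direction depended on how many peaks each list held. With every list kept to its 29171 strongest peaks, 254 regions were TCPOBOP-only and 178 vehicle-only, and the other splits gave 272 regions at most. Among strong regions, 22 were TCPOBOP-only and 7 vehicle-only. A TCPOBOP-only region had 4 libraries in which to be strong and a vehicle-only region 3, so these counts are not on equal terms. Ranked by −log10 q they numbered 5 and 0, and with strength required in every library 0 and 0.

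The TCPOBOP-only H3K27ac regions ranked highest at 27 h lay on chromosome 3 (113022488 to 113022854), chromosome 12 (80204414 to 80205649) and chromosome 16 (88635100 to 88635573). Their fold enrichments were 5.83 to 9.46, 5.50 to 9.16 and 5.84 to 8.25 over the 4 TCPOBOP libraries. All 10 named regions had fold enrichments between 5.28 and 9.52. In 8 of the 10, no library of that time had H3K4me3. In the mice of 3 h, 7 of the 10 were called in a larger share of TCPOBOP than of vehicle libraries, 0 in a smaller share, 1 in an equal share, and 2 in no library. The first vehicle-only regions lay on chromosome 9 (60797607 to 60798157), at 7.51- to 8.40-fold, and chromosome 14 (37677164 to 37677425), at 6.19- to 8.02-fold. Of the 7 named vehicle-only regions, 5 were called in equal shares of both conditions at 3 h, 1 in a larger share of vehicle libraries and 1 in a smaller.

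The chromosome 12 region (80204414 to 80205649) was named for opposite directions in different marks. At 27 h, H3K27ac was called there in all 4 TCPOBOP livers and 0 of 3 vehicle livers, and H3K4me1 in 0 of 4 and all 3. In the livers of 3 h, H3K27ac was called in 3 of 3 TCPOBOP and 1 of 3 vehicle livers, and H3K4me1 in all 3 of each. H3K4me3 was called in 2 of 4 TCPOBOP and 0 of 3 vehicle livers at 27 h, and in 1 of 3 and 0 of 3 at 3 h. As the vehicle-only H3K4me1 region it spanned 80204592 to 80205450, with 4.76- to 7.63-fold enrichment. TCPOBOP replicates 3 and 4 of 27 h had H3K4me1 peaks beside it, less than 1 kb away, at 80203743 to 80204102 and 80203937 to 80204238, so a 1 kb limit would not count it as vehicle-only. Absence here means that no peak passed the authors' threshold at these depths.

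**Figure D1:**
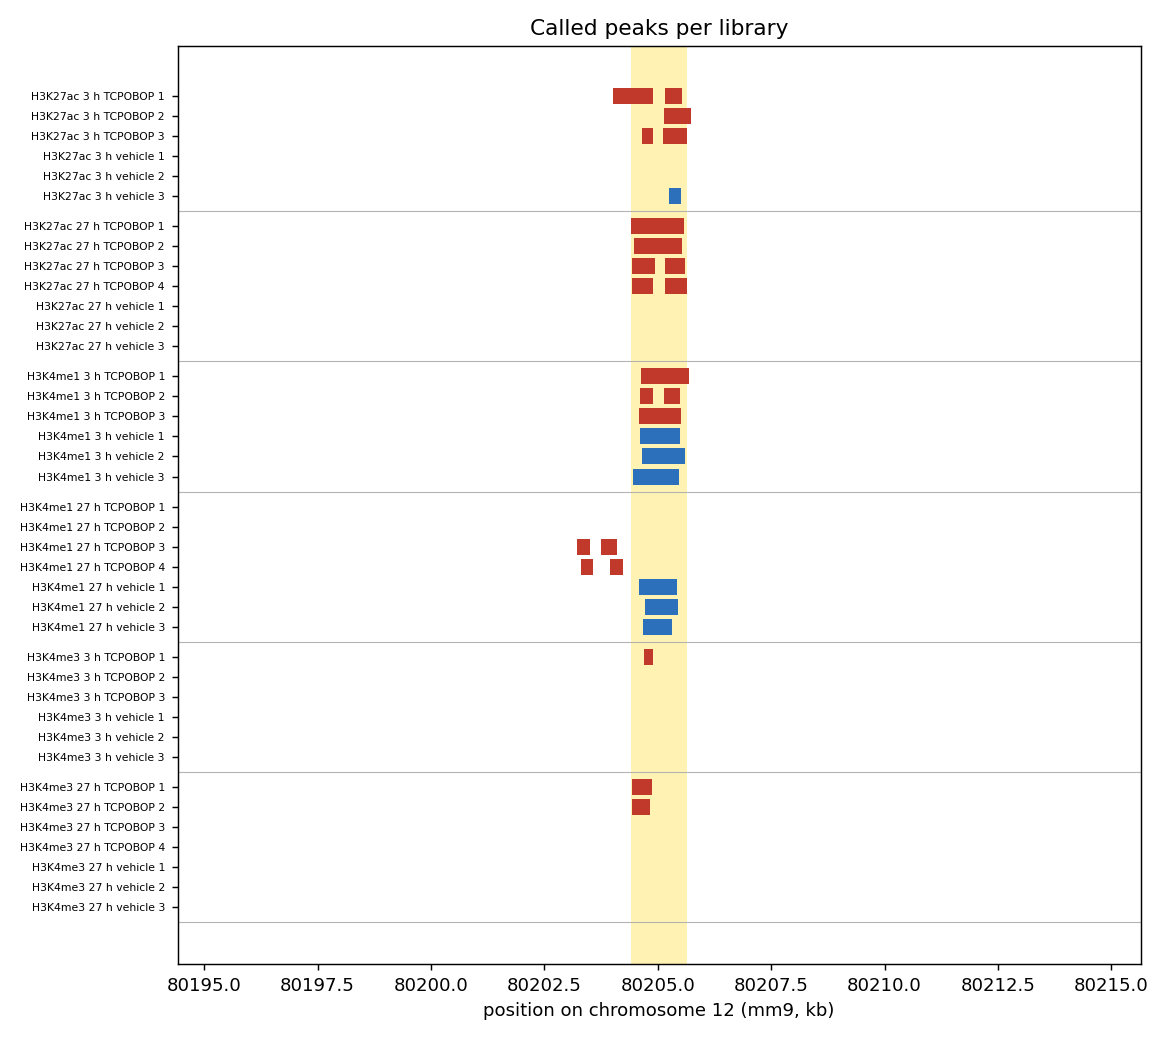
Peaks called in each of the 39 libraries on chromosome 12 from 80194414 to 80215649 (mm9), with position in kb on the horizontal axis and 1 line per library. Red bars are peaks of TCPOBOP libraries and blue bars peaks of vehicle libraries; the shaded band is the region 80204414 to 80205649, where at 27 h all 4 TCPOBOP libraries have H3K27ac and all 3 vehicle libraries have H3K4me1.

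At 3 h, H3K27ac was called in all TCPOBOP and no vehicle livers in 264 regions and in the reverse in 434, together 1.02% of 68497 regions. Of the 10 splits, 3 gave as many regions as the real 698, and the highest other split gave 872. With lists of equal length, 325 and 366 regions were found, together 691, which only the real split reached (634 at most in the others); 10 splits cannot give a share under 0.05 for any mark. Strong regions numbered 10 and 20. The TCPOBOP-only region ranked first lay on chromosome 10 (110315429 to 110316039), with 5.32- to 7.27-fold enrichment in the 3 TCPOBOP libraries, and was called at 27 h in 3 of 4 TCPOBOP and 1 of 3 vehicle livers. A TCPOBOP-only region on chromosome 2 (11385917 to 11386310) was called at 27 h in 2 of 4 and 0 of 3 livers. The 27 h TCPOBOP-only region beside it, less than 1 kb away at 11386469 to 11386840, was also called in 3 of 3 TCPOBOP and 2 of 3 vehicle livers at 3 h. A 1 kb limit would thus not count the 3 h region as TCPOBOP-only. The vehicle-only regions ranked first lay on chromosome 12 (72819760 to 72820102), at 11.9- to 15.01-fold, and chromosome 11 (101465928 to 101466152), at 8.29- to 12.1-fold. At 27 h the former was called in every library of both conditions. Of the 10 named TCPOBOP-only regions, 5 were called at 27 h in a larger share of TCPOBOP than of vehicle libraries, 2 in a smaller share and 3 in no library. Of the 10 vehicle-only ones, 5 were called in a larger share of vehicle libraries, 2 in a smaller, 1 in an equal share and 2 in no library. All 10 named TCPOBOP-only regions had H3K4me1 in at least 1 library of 3 h, and 8 had it in every library.

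H3K4me1 at 3 h was TCPOBOP-only in 317 regions and vehicle-only in 827. Of the 10 splits, 3 gave as many as 1144 regions, and the highest other split gave 1250. With lists of equal length the total was 1011, which only the real split reached (984 at most in the others). At 27 h, 133 regions were TCPOBOP-only and 571 vehicle-only, and 6 of 35 splits gave as many as 704, with 997 at most, and with lists of equal length 11 of 35 gave as many as 563, with 799 at most. Strong regions numbered 55 and 72 at 3 h, and 43 and 107 at 27 h. At 3 h, TCPOBOP-only regions on chromosome 4 at 34857469 to 34858117 and at 47704323 to 47704780 were enriched 4.74- to 8.45-fold and 5.42- to 6.66-fold. A vehicle-only region on chromosome 7 (13404259 to 13404684) was enriched 6.93- to 7.75-fold. At 27 h, the first-ranked TCPOBOP-only region lay on chromosome 1 (188141128 to 188141761), at 4.43- to 6.47-fold, and all 6 livers of 3 h had H3K4me1 there. Of the 20 H3K4me1 regions named at 27 h, 8 TCPOBOP-only and 9 vehicle-only regions had no H3K27ac peak in any library of that time.

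H3K4me3 had few TCPOBOP-only regions. At 3 h, 4 regions were TCPOBOP-only and 418 vehicle-only, and at 27 h 20 and 43. Simulated lists of the real lengths gave, beside the planted regions, 0 and 275 by chance at 3 h. The 0 was fixed by construction, since the longest list, a vehicle list, held every unplanted region. The simulation thus cannot show how far list length accounts for the real asymmetry. Of the 10 splits at 3 h, 3 gave as many as 422 regions, and the highest other split gave 888. Of the 35 splits at 27 h, 9 gave as many as 63, and the highest other gave 109. With lists of equal length the 3 h counts were 37 and 130, and this total of 167 was reached by the real split alone (162 at most in the others), while 3 of 35 splits gave as many as 63 at 27 h (67 at most). No H3K4me3 condition-only region was strong at either time, so none was named. The median width of regions called in every library was 770 bp at 3 h and 1014 bp at 27 h, against 358.5 bp and 429 bp for vehicle-only regions.

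**Figure D2:**
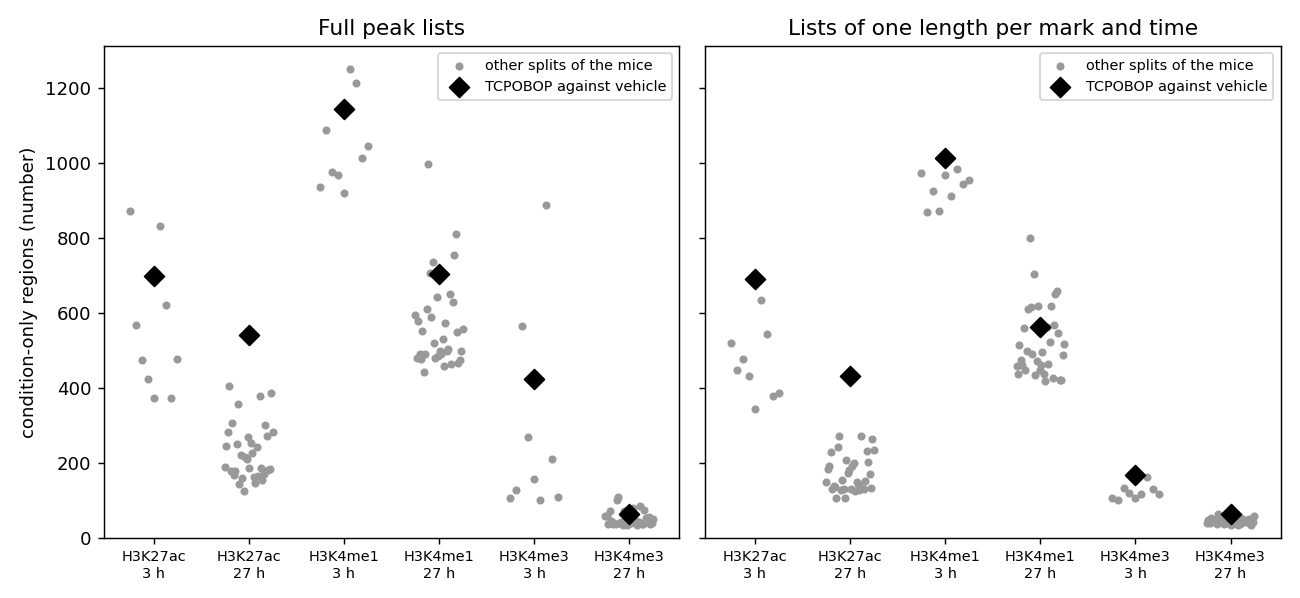
Number of condition-only regions for each mark and time, with full peak lists on the left and with all lists of a mark and time kept to the length of the shortest on the right. Black diamonds are TCPOBOP against vehicle and grey points the other splits of the same mice; with full lists the diamond lies above all other splits only for H3K27ac at 27 h (541), and with lists of equal length for H3K27ac at 27 h (432) and for H3K27ac (691), H3K4me1 (1011) and H3K4me3 (167) at 3 h.

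Most H3K27ac condition-only regions at 3 h had H3K4me1 in both conditions, a smaller share than of regions with H3K27ac in every library. Among TCPOBOP-only H3K27ac regions, 64.4% (95% interval 58.3 to 70.2, 264 regions) had H3K4me1 in both conditions at 3 h, and 48.0% (40.8 to 55.2, 196 regions) at 27 h. Among vehicle-only regions, 62.0% (57.2 to 66.6) had it at 3 h and 40.3% (35.1 to 45.7) at 27 h. Of regions with H3K27ac in every library, 76.2% (75.7 to 76.7) had it at 3 h and 38.8% (38.1 to 39.5) at 27 h. H3K4me3 was rarer at condition-only regions than at regions with H3K27ac in every library. In the condition with H3K27ac it was present at 4.55% (2.37 to 7.81) of TCPOBOP-only regions at 3 h and at 7.14% (3.96 to 11.7) at 27 h. The corresponding vehicle-only shares were 10.1% (7.46 to 13.4) and 5.22% (3.12 to 8.12). Of regions with H3K27ac in every library, 48.0% had H3K4me3 in TCPOBOP livers and 57.0% in vehicle livers at 3 h, and 56.9% and 57.0% at 27 h. Those regions were wider, with a median of 898 bp at 3 h against 416.5 bp and 425.5 bp for TCPOBOP-only and vehicle-only regions, and 891 bp at 27 h against 555 bp and 453 bp. A mark was called in a condition when at least 2 of its libraries had a peak, which at 27 h meant 2 of 4 TCPOBOP but 2 of 3 vehicle libraries. The shares of the 2 conditions at 27 h are thus not on equal terms. The intervals do not include the spread between mice.

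Few regions were condition-only at both times, and the times differ in mice and in chromatin preparation. For H3K27ac, 7 regions were TCPOBOP-only at both times, where independent lists over the 46715 regions present at both times would share 0.511. Another 2 were vehicle-only at both times (2.01 for independent lists), 2 were vehicle-only at 3 h and TCPOBOP-only at 27 h (1.11), and 0 changed the other way (0.924). The same direction was kept by 9 of 11 regions, 81.8% (48.2 to 97.7), an interval that includes the 55.3% of independent lists. Among them, TCPOBOP-only regions were named on chromosome 5 (46042884 to 46043363), chromosome 18 (51620626 to 51621511) and chromosome 19 (39180534 to 39181112). Their fold enrichments at 27 h were 5.63 to 7.79, 5.76 to 7.47 and 5.60 to 8.13. For H3K4me1, 5 regions were vehicle-only (3.09 for independent lists) and 0 TCPOBOP-only (0.323) at both times, and 2 changed from TCPOBOP-only to vehicle-only (1.35), so 71.4% (29.0 to 96.3) kept the direction, against 62.1% for independent lists. A region on chromosome 9 (65428314 to 65428765) was TCPOBOP-only for H3K4me1 at 27 h and had H3K27ac at 3 h in 3 of 3 TCPOBOP and 0 of 3 vehicle livers. Regions on chromosome 8 (67488781 to 67489199) and chromosome 13 (58857179 to 58857536) were vehicle-only for both H3K4me1 and H3K27ac at 27 h, and had H3K27ac at 3 h in 1 of 3 TCPOBOP and 0 of 3 vehicle livers, and in 2 of 3 and 1 of 3. A second region on chromosome 8 (122158988 to 122159638), vehicle-only for H3K4me1 at 27 h, had H3K4me1 at 3 h in 0 of 3 and 2 of 3 livers and overlapped a wider region vehicle-only there at 3 h. A region on chromosome 1 (58448697 to 58449035) was vehicle-only for H3K27ac at 27 h and had H3K4me3 at 3 h in 0 of 3 and 3 of 3 livers, and H3K27ac at 3 h in 2 of 3 and 3 of 3. For H3K4me3, 3 regions were vehicle-only at both times (0.461 for independent lists).

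Condition-only H3K27ac regions were also followed into livers of the other time. Of the TCPOBOP-only regions of 27 h, 52.0% had a peak in TCPOBOP libraries of 3 h and 36.7% in vehicle libraries of 3 h, as means over libraries. Of the vehicle-only regions, 44.3% and 52.8% had one. The difference between the region sets was 7.69 ± 6.57 points in TCPOBOP livers and -16.0 ± 1.75 in vehicle livers (SD, n = 3 each, exact two-sided p = 0.1, the lowest possible). For H3K27ac regions of 3 h in livers of 27 h, it was -5.95 ± 7.38 points (SD, n = 4) and -22.0 ± 7.00 (SD, n = 3, exact two-sided p = 0.0571, the lowest possible). In each case every TCPOBOP library lay above every vehicle library, also with lists of equal length. H3K4me3 regions of 27 h differed by 20.6 points between TCPOBOP and vehicle livers of 3 h, with no overlap of libraries, but by 0.169 points with lists of equal length (exact two-sided p = 1), where the libraries overlapped. Of the 35 splits of the 27 h mice, 4 gave as large a difference with full lists, and all 35 with lists of equal length. In the other 3 combinations of a mark with the other time the libraries overlapped. Over all 30 combinations of region set and libraries, every TCPOBOP library lay above every vehicle library in 7 and below in 2, and the lowest adjusted p was 0.333.

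**Figure D3:**
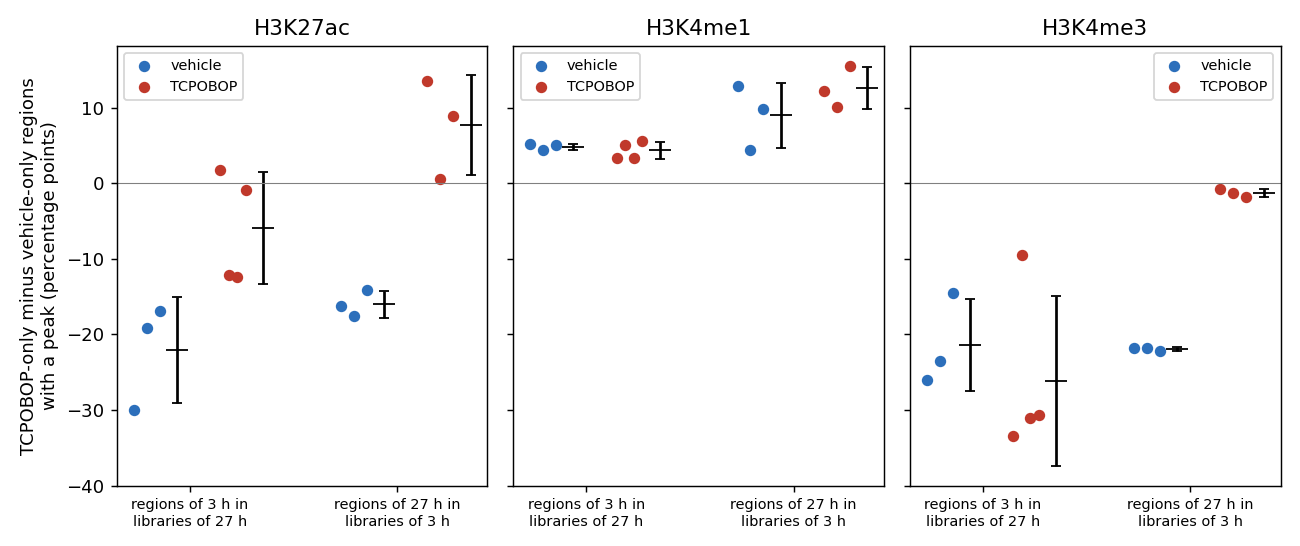
Percentage of TCPOBOP-only regions with a peak minus that of vehicle-only regions, in percentage points on the vertical axis, for each library of the time in which the regions were not defined. Blue points are vehicle and red points TCPOBOP libraries, and black bars give the mean ± SD; for H3K27ac, all TCPOBOP libraries lie above all vehicle libraries in both directions.

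In 10 kb windows, 3 windows gained called H3K27ac length after TCPOBOP when both times were fitted together. On chromosome 19 (39280001 to 39290000) the log2 difference was 2.63 ± 0.26 (SE, limma adjusted p = 0.00266). Called length there was 1235 ± 92.9 bp after TCPOBOP and 103 ± 178 bp after vehicle at 3 h (SD, n = 3 each), and 1278 ± 405 bp (SD, n = 4) and 0 bp (n = 3) at 27 h. On chromosome 6 (87160001 to 87170000) it was 1.27 ± 0.16, and on chromosome 12 (80200001 to 80210000), the window of the region described above, 2.31 ± 0.30 (SE, limma adjusted p = 0.0219 each). In all 3 windows, each of the 7 TCPOBOP libraries exceeded every vehicle library of its time. The windows were picked by the difference in these same libraries, so this adds no independent support. No window passed as lower after TCPOBOP, and 1504 of 16708 had an unadjusted p under 0.05. With 50 bp in place of 200 bp added before the log, 0 windows passed, and without any of the 7 TCPOBOP libraries in turn, or without vehicle replicate 1 of 27 h, 1 window passed.

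No window passed for H3K4me1 or H3K4me3 over both times, nor for any mark in the separate fits by limma. On simulated windows with 200 planted changes of 1 log2 unit, the separate fits recovered 0% for H3K4me1 at either time and 30.0% for H3K27ac at 3 h, so changes of that size can be missed there. The numbers of windows with an unadjusted p under 0.05 were 2029 of 29318 for H3K4me1 and 828 of 9673 for H3K4me3 over both times. In the separate fits they were 1077 and 1252 for H3K27ac at 3 h and 27 h, 2050 and 1003 for H3K4me1, and 795 and 387 for H3K4me3. The median difference over windows was -0.23 log2 units for H3K4me3 at 3 h, -0.14 for H3K4me1 at 27 h and -0.12 for each of these marks over both times, and -0.09 to -0.02 in the other fits. With library means subtracted, 7 H3K27ac windows passed at 27 h, all higher after TCPOBOP, and 5 over both times, and 1 H3K4me3 window passed at 27 h, on chromosome 7 (26680001 to 26690000), at 1156 ± 235 bp (SD, n = 4) after TCPOBOP and 0 bp (n = 3) after vehicle (limma adjusted p = 0.0400, and 0.0690 without subtraction).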

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

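The tests of list length and the splits of condition-only regions were chosen after the result was seen, while the tests of differences between mice and the splits of windows were set before theirs was; the windows themselves were added after the data were examined.

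At a single H3K4me1 window on chromosome 5 (140500001 to 140510000), the TCPOBOP effect differed between the times (limma interaction, log2 difference of effects at 27 h minus 3 h -2.94 ± 0.30, SE, adjusted p = 0.00172). Called H3K4me1 length was 1732 ± 284 bp after TCPOBOP and 1694 ± 84.9 bp after vehicle at 3 h (SD, n = 3 each), and 0 bp (n = 4) and 1316 ± 47.6 bp (SD, n = 3) at 27 h. The separate fit of 27 h did not call the window (log2 difference -2.92 ± 1.45, SE, limma adjusted p = 0.837). It was the only window of the 3 marks with such a difference, and kept its call with library means subtracted, with 50 or 1000 bp added and without any single library (limma adjusted p of 0.0296 at most). All 4 TCPOBOP libraries of 27 h had 0 bp there, so leaving out any of them could not change the effect (-2.94 each time). Of 100 drawn splits of the mice within each time, 4 gave as many as 1 window, the real one included, with 1 in the highest other. Other splits thus matched the real count, and the share was not adjusted for the 3 marks, so chance could not be excluded. For H3K4me3, the same kind of fit gave 357 windows in another split, where the real one gave 0. The times also differ in chromatin preparation.

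For H3K4me3 regions of 3 h, TCPOBOP replicate 2 of 27 h lay apart from the other 3 TCPOBOP libraries. The difference between TCPOBOP-only and vehicle-only regions with a peak was -9.45 points in it and -33.5, -31.1 and -30.6 points in the others, a gap of 0.881 of the range, above Dixon's 95% critical value. The value rests on only 4 TCPOBOP-only regions. It was 1 of 18 values examined in this way, 6 measures for each of 3 marks in the same 4 mice, and chance marks about 1 in 20.

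Vehicle-only regions outnumbered TCPOBOP-only regions in all 6 comparisons, and vehicle lists were also longer on average in all 6. With lists of equal length, 5 of the 6 comparisons kept the excess and H3K27ac at 27 h turned, to 254 TCPOBOP-only against 178 vehicle-only regions. Longer lists may thus account for part of the excess; a fall to 3 or fewer would have fitted that cause and an excess in all 6 would have excluded it, so the test left it open. Groups of 27 h were unequal, with 4 TCPOBOP and 3 vehicle libraries. The vehicle-only rule was thus easier to meet for weakly called regions. Leaving out each TCPOBOP library in turn, which leaves 3 against 3, kept the excess. Vehicle-only regions numbered 428 to 670 against 259 to 362 for H3K27ac, and 842 to 1155 against 305 to 370 for H3K4me1. For H3K4me3 they numbered 67 to 88 against 30 to 40. Group size as the whole cause was thus argued against for full lists only. A loss of marks after TCPOBOP stays open and was not separately tested.

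The number of H3K27ac condition-only regions at 27 h, 541, was reached by 1 of 35 splits, the real one, and the highest other split gave 404, so chance can be excluded only for this comparison taken alone, as the share was not adjusted for the 6 comparisons. List length as the whole cause was argued against, since with lists of equal length again 1 of 35 splits, the real one, gave as many as 432, against 272 at most. Differences between individual mice stay open. In the other mice of 3 h, the regions separated TCPOBOP from vehicle livers by 23.7 points, which 1 of 35 splits reached (19.9 at most in the others), but with lists of equal length by 19.5 points, which 3 of 35 splits reached (20.2 at most). The first form was set to exclude this cause but left list length free at 3 h, so it cannot exclude it alone, and a response of H3K27ac to TCPOBOP remains a hypothesis.

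For the 3 windows with more called H3K27ac over both times, 1 of 100 drawn splits of the mice within each time, the real one, gave as many, and the highest other split gave 2, so chance can be excluded only for this count taken alone and at the reported setting. The share was not adjusted for the 9 such fits or for the choice of scaling, and for H3K4me3 over both times another split gave 4 windows where the real one gave 0. The choice of the added length could decide the calls, since 0 windows passed with 50 bp, where chance is not excluded, and 3 with 1000 bp, and subtracting library means gave 5. Without any of the 7 TCPOBOP libraries in turn, or vehicle replicate 1 of 27 h, 1 window passed, and fewer libraries alone lower the power of the fit. In simulated data the same fit made 16 false calls beside 196 recovered changes of 2 log2 units. False calls grow with the number of calls under this adjustment, so that count cannot be set beside 3 calls. Any of the 3 windows may still be false, and a gain of H3K27ac at these windows is a hypothesis.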

How the results depend on the processing

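The alternatives of overlap, threshold, list length, strength, distance, autosomes and pairing were fixed before the data were examined, except as named here. Every alternative for regions followed into the libraries of the other time, the −log10 q limit for peak number, the tests without single libraries (except for condition-only counts), the settings of the windows and the strong subset for marks were chosen after the result was seen. Condition-only counts were given under 162 alternatives, of which 131 moved by over 1.5 times; of 75 alternatives of overlap, 8 moved, 10 weakened and 6 turned, and windows moved in 18 of 111. Autosomes alone changed no count by over 1.5 times. The cause of a change was not tested except where the construction of the alternative gives it, and depth limits which weak peaks a list can hold.

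Condition-only counts follow as TCPOBOP-only and vehicle-only regions. When any peak of the other condition within 1 kb excluded a region, H3K27ac gave 101 and 226 at 3 h and 130 and 191 at 27 h, H3K4me1 197 and 457, and 68 and 340, and H3K4me3 222 vehicle-only at 3 h and 23 at 27 h. When a peak in all but 1 library of a condition sufficed, which by construction adds regions, H3K27ac gave 1606 and 2324, and 599 and 2100, H3K4me1 2339 and 4542, and 968 and 3604, and H3K4me3 220 and 2521, and 75 and 388. Lists of equal length moved H3K27ac at 27 h to 178 vehicle-only, H3K4me1 at 27 h to 211 and 352, and H3K4me3 at 3 h to 37 and 130.

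A strength limit by construction lowers the counts. Strong regions (shortest list divided by 4) numbered 10 and 20, and 22 and 7 for H3K27ac, 55 and 72, and 43 and 107 for H3K4me1, and 0 and 0 at both times for H3K4me3. Ranked by −log10 q, they numbered 1 and 3, and 5 and 0 for H3K27ac, 20 and 37, and 49 and 101 for H3K4me1, and 0 for H3K4me3. With a divisor of 10 they numbered 0 and 2, and 0 and 0 for H3K27ac, 10 and 16, and 12 and 29 for H3K4me1, and 0 for H3K4me3. With strong regions at both times, or at 3 h only, 0 regions were shared between times in either direction for any mark.

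Leaving out each library in turn raised every count by construction, since fewer libraries had to match. For H3K27ac at 3 h the lowest and highest counts were 406 and 865 TCPOBOP-only and 724 and 1368 vehicle-only, and at 27 h 259 and 362, and 428 and 1110. For H3K4me1 they were 593 and 1266, and 1379 and 2646 at 3 h, and 305 and 443, and 842 and 1824 at 27 h. For H3K4me3 they were 10 and 172, and 467 and 1889 at 3 h, and 26 and 92, and 67 and 276 at 27 h.

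The share of peaks found in the other condition moved with a fraction of 0.5 of the peak required, to 71.6% for H3K27ac at 3 h, 69.0% and 52.5% for H3K4me1 at 3 h and 27 h, and 82.0% for H3K4me3 at 27 h. With both lists limited to −log10 q of at least 10 it moved to 82.1%, 58.5%, 30.2% and 89.7% in that order. The excess within conditions for H3K27ac at 27 h was 1.24 points with a fraction of 0.5, 1.42 with −log10 q of at least 10 and 1.02 with lists of equal length (exact one-sided p = 0.0571 each). Without single libraries it was 0.796 (TCPOBOP replicate 1) to 1.62 (vehicle replicate 1), where the splits are too few for an exact p under 0.05. Without single libraries the excess was -0.247 to 0.845 for H3K4me1 at 3 h, negative without each vehicle library, and -1.04 to 0.766 for H3K4me1 at 27 h, positive without TCPOBOP replicates 2 or 3. For H3K4me3 at 3 h it was -0.140 (vehicle replicate 2) to 1.62. The difference in peak number ran from -3686 to 1100 for H3K27ac at 3 h (1100 without vehicle replicate 3, 171 without TCPOBOP replicate 2), and from -1297 to 75 for H3K4me3 at 27 h (75 without vehicle replicate 2).

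Within 1 kb, H3K4me1 in both conditions was found at 82.2% and 78.6% of TCPOBOP-only and vehicle-only H3K27ac regions at 3 h, and at 64.3% and 58.3% at 27 h. H3K4me3 in the condition with H3K27ac was found at 12.1% and 20.05% at 3 h and at 10.7% of vehicle-only regions at 27 h. At strong regions the H3K4me1 shares were 100% (TCPOBOP-only, 3 h), 63.6% and 71.4% (27 h), and the H3K4me3 shares 20% and 30% at 3 h and 13.6% and 42.9% at 27 h. At the 2 vehicle-only regions left with a divisor of 10 at 3 h, both shares were 50%. H3K4me1 regions of 3 h in libraries of 27 h turned from -0.483 points between conditions to 0.353 with lists of equal length (exact p = 0.743) and 0.0655 within 1 kb (exact p = 0.971).

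Subtracting library means from windows gave 7 calls for H3K27ac at 27 h, 5 over both times and 1 for H3K4me3 at 27 h. With 1000 bp added there were 9 and 1 at 27 h for these marks, and with 50 bp 0 for H3K27ac over both times. Without single libraries there were 0 to 3 calls for H3K27ac at 27 h (3 without vehicle replicate 1, 2 without vehicle replicate 3) and 0 to 1 for H3K4me3 at 27 h (1 without vehicle replicate 1 or 2). For H3K27ac over both times there were 1 to 4, with 1 call without any of the 7 TCPOBOP libraries in turn or vehicle replicate 1 of 27 h. Windows whose effect differed between the times numbered, without single libraries, 0 to 2 for H3K27ac, 1 to 2 for H3K4me1 (2 without TCPOBOP replicate 2 of 27 h) and 0 to 34 for H3K4me3 (34 without TCPOBOP replicate 1 of 3 h). The liver numbers in the labels name mice and were not used as pairs in the reported fits. Same-numbered livers of the 2 conditions correlated with r from -0.0600 to 0.207 over windows, and in no mark and time did every pair exceed 0.1. For H3K4me1 at 3 h and H3K4me3 at 27 h only, every TCPOBOP liver with a same-numbered vehicle liver correlated best with it. Some pairing is thus not excluded. With the liver number as a block, which leaves out TCPOBOP replicate 4 at 27 h, 0 windows were called in all 6 fits, as without it.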

Other observations

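The tallies of regions shared between marks, their splits and the values by chromatin preparation were chosen after the result was seen, and the splits of windows were set before theirs was.

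At 27 h, 3 regions were TCPOBOP-only for H3K27ac and vehicle-only for H3K4me1. Beside the region on chromosome 12 (80204414 to 80205649), they lay on chromosome 11 (107324733 to 107325081) and chromosome 5 (89647745 to 89648191), and were named after their values were seen. H3K27ac there was enriched 3.51- to 4.43-fold and 3.45- to 4.22-fold over the 4 TCPOBOP libraries. In the livers of 3 h, H3K27ac was called at the chromosome 11 region in 3 of 3 TCPOBOP and 0 of 3 vehicle livers, and at the chromosome 5 region in all 3 of each. Of the 35 splits of the 27 h mice, only the real one gave as many as 3 such regions, and the highest other split gave 2. Regions vehicle-only for H3K4me1 and TCPOBOP-only for H3K4me3 at 27 h numbered 2, which no other split reached (1 at most). The other 4 tallies of opposite directions, over the pairs of marks at each time, were 0 or 1, and other splits gave as many. These were 12 tallies in all with those of the same direction, and the share was not adjusted for them.

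Regions with the same direction in a pair of marks were also few. At 27 h, 1 region was TCPOBOP-only for both H3K27ac and H3K4me1, and 5 were vehicle-only for both, and 2 of 35 splits gave as many as 6 such regions, with 6 in the highest other, so chance could not be excluded. The region shared after TCPOBOP lay on chromosome 10 (40981110 to 40981588), with 5.95- to 7.64-fold enrichment of H3K27ac, and was called for H3K27ac at 3 h in 3 of 3 TCPOBOP and 2 of 3 vehicle livers. At 3 h, 1 region was TCPOBOP-only and 7 were vehicle-only for both marks, against 7 in all in the highest other split, and the 10 splits allow no share under 0.05. A vehicle-only region of both marks lay on chromosome 18 (70705626 to 70706395), with 4.92- to 7.23-fold enrichment of H3K4me1. H3K27ac with H3K4me3 shared 2 regions at 3 h and 1 at 27 h, and H3K4me1 with H3K4me3 shared 1 and 0. None was condition-only in the same direction for more than 2 combinations of mark and time.

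Fragment and peak sizes of H3K4me3 differed between the times, which differ in mice and chromatin preparation together. The labels also give the H3K4me3 libraries of 3 h a series code of their own, unlike the other libraries of 3 h and those of 27 h. Its meaning is not given, and its part in the difference cannot be told apart. H3K4me3 fragments measured 141 to 150 bp in the 6 libraries of nuclei at 3 h and 196 to 209 bp in the 7 libraries of frozen tissue at 27 h, and the median peak width was 326 to 377.5 bp and 569.5 to 652 bp. For H3K27ac the fragments were 174 to 190 bp and 196 to 207 bp, and the peak widths overlapped, at 401 to 452 bp and 423 to 437 bp. H3K4me1 fragments overlapped, at 177 to 191 bp and 190 to 201 bp, and peaks were wider at 3 h, at 418 to 460 bp, than at 27 h, at 339 to 374 bp. Regions called in every library made up 35.9% and 32.1% of H3K27ac regions at 3 h and 27 h, 36.6% and 15.9% of H3K4me1 regions, and 28.6% and 50.2% of H3K4me3 regions.

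For the other counts of condition-only regions, 6 of 35 splits gave as many for H3K4me1 at 27 h (704, highest other 997) and 9 of 35 for H3K4me3 at 27 h (63, highest other 109), so chance could not be excluded. At 3 h, 3 of 10 splits gave as many for each of H3K27ac (698, highest other 872), H3K4me1 (1144, highest other 1250) and H3K4me3 (422, highest other 888), and 10 splits cannot give a share under 0.05. With lists of equal length the real split at 3 h alone reached its number for each of these marks (691, highest other 634; 1011, highest other 984; 167, highest other 162), under the same limit. The separate window fits called 0 windows, so all 10 splits at 3 h and all 35 at 27 h gave as many for each mark, with 0 in the highest other except 1 for H3K4me3 at 27 h. Over both times, all 100 drawn splits gave as many as the 0 windows of H3K4me1 and of H3K4me3, with 1 and 4 in the highest other. All 100 likewise gave as many as the 0 windows whose effect differed between the times for H3K27ac and for H3K4me3, with 2 and 357 in the highest other. The cause of the H3K4me3 split with 357 windows was not tested. Across windows, the changes at 3 h and 27 h correlated with r = 0.170 for H3K27ac, 0.0201 for H3K4me1 and 0.0630 for H3K4me3; windows are not independent replicates.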
